A study of Mus musculus with 22 samples.

How the data were processed

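Gene expression was measured in the hypothalamus of 22 male C57BL/6 mice, with 1 array per mouse. Lewis lung carcinoma is a transplantable mouse tumour. Per the labels' protocols, tumour cells were injected into the muscle of a hind leg, and hypothalami were taken on day 10 (5 mice), day 14 (7 mice) or day 17 (6 mice), and on day 14 from 4 controls. The tumour-bearing groups of days 10 and 17 therefore had no controls of their own day. RNA with an integrity number above 8 was hybridised, per the labels' protocols. The deposited values are log2 values that the authors obtained with RMA, per the submitters' processing notes, which corrects the background, normalizes between arrays and summarizes probes into probe sets. The version of RMA, the genome build and the annotation were not given in the sources used here.

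The deposited table held 35556 probe sets. The platform annotation paired 21218 of them with 1 gene and 1881 with several genes, and 12457 were unnamed here. An Entrez identifier of the RefSeq table (GRCm38.p6, used for names only) was found for 21185 probe sets and changed 0 symbols. The probe set with the highest mean over all arrays stood for each of 18820 genes, of which 1386 had more than 1 probe set. Agrp and Pmch had no probe set of their own in this pairing and were not analysed here. No filter on low values was applied. The 95th percentile of 1182 olfactory and vomeronasal receptor probe sets, 3.87 on the log2 scale, served as a measure of background, and 13790 genes had a mean above it. Array medians ran from 5.27 to 5.34, correlations between arrays over probe sets ran from 0.980 to 0.995, and 0 pairs of arrays were identical. The number of arrays limits the precision.

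One linear model with 4 group means was fitted to all 22 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes without a trend, 18 residual degrees of freedom). The contrasts set each tumour-bearing group against the controls, the tumour-bearing groups against each other, and a straight line over days 10, 14 and 17 among tumour-bearing mice, and a moderated F test asked for any difference between groups. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. The labels describe separate mice. Changes are log2 differences, tumour minus control, with the standard error (SE) of the fit. Errors of group means are standard deviations (SD).

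A total of 35 gene lists, covering feeding, monoamine, stress, immune and metabolic genes and markers of cell types and neighbouring tissue, were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists). The list test was repeated with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. Npy, Pomc, Cartpt and Hcrt were also tested with exact permutation tests, a family of 12 tests. Groups, tests, lists, the first set of alternative settings and the rule for named genes were set before the data were examined. The rule named the 10 largest rises and falls past the threshold per comparison with control (5 between days, and where fewer than 5 passed, the 5 smallest p in each direction as values), up to 4 members past the threshold per list or otherwise the 2 with the smallest p, and always the feeding genes and Tph2, Slc6a4, Maoa, Htr1a, Htr1b, Htr2a, Htr2c and Htr7. Predicted genes, small RNAs and olfactory or vomeronasal receptors were counted but not named. Genes named by the rule without passing are given by example. Rbm3 was chosen after its values were seen, and Cirbp was chosen for a test of the same pattern before its own values were looked at.

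The first set of alternative settings changed the variance moderation, array weights, scaling, low-value filter, probe set rule, samples in the fit, threshold and list test, added the replicate number as a block or a term for the run of accessions, and left out each array in turn. Robust variance estimation was tried for the gene counts and not for the lists. The run term split the first 9 and the last 13 samples, a possible batch that the labels do not state. Chosen after the data were seen were each run alone, the mean of the thalamus marker list as a covariate, and leaving out the 4 arrays highest in those markers. The fit was tested on simulated data with the real gene means and spreads. For tumour day 17 against control, it recovered 82.8% of genes simulated with a log2 change of 0.5 and 99.2% of those with a change of 1, and 5.18% of calls were false. Simulated genes were independent of each other, which real genes are not.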

Results

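Hypothalamic RNA of mice carrying Lewis lung carcinoma was compared with that of tumour-free controls, in a series whose title concerns food intake and serotonin signalling. The data were log2 array values of 18820 genes in 4 controls, 5 mice of tumour day 10, 7 of day 14 and 6 of day 17. Day 14 was the only day with controls, so the comparisons of days 10 and 17 also contain a difference in day.

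On day 10, genes of inflammation and of the interferon response were higher in tumour-bearing mice. Lcn2, which encodes the iron-binding acute-phase protein lipocalin 2, rose by 2.21 ± 0.39 (SE, log2, n = 5 and 4, limma adjusted p = 0.028). Ptgs2, the inducible cyclooxygenase, rose by 1.15 ± 0.20, and the chemokine genes Cxcl9 and Cxcl10 rose by 1.21 ± 0.23 and 0.93 ± 0.17. Oasl2, Ifitm3 and H2-K1, which interferon induces, rose by 0.86 ± 0.12, 1.06 ± 0.18 and 0.68 ± 0.12. The ceramidase gene Acer2, Zbtb16, Il1r1, Osmr and Ifi27l2a also rose, and Kcns2, a potassium channel subunit, fell by 0.56 ± 0.10. Of 36 measured interferon-stimulated genes, 5 rose and 0 fell, or 24 and 0 adjusted over the list alone. The list was called higher (camera adjusted p = 3.01e-22), with adjusted p = 0.0578 with an estimated correlation. Of 41 acute-phase and cytokine genes, 5 rose, or 10 adjusted over the list alone (camera adjusted p = 6.85e-14, and adjusted p = 0.0503 with an estimated correlation). Of 24 glucocorticoid-responsive genes, 2 rose, or 7 adjusted over the list alone (camera adjusted p = 3.73e-10, and adjusted p = 0.144 with an estimated correlation). Among the 13 named genes, which were chosen for passing, all 5 tumour-bearing mice lay beyond every control in 11. Of the cell type markers, 14 of 14 circulating leukocyte, 13 of 15 microglia and 12 of 12 meningeal fibroblast markers had a higher mean. In each of these lists 0 genes passed the threshold in limma, and 0 adjusted over the list alone. The lists were called higher (camera adjusted p = 0.00169, 0.0477 and 0.00468, and adjusted p = 0.181, 0.521 and 0.541 with an estimated correlation). With each of the 22 arrays left out in turn, the microglia call was lost in 10 fits and the meningeal fibroblast call in 2 (highest camera adjusted p = 0.169 and 0.136). The mean of the leukocyte list was 3.50 in controls, below the background measure of 3.87. In all, limma called 20 genes changed, 19 up and 1 down, and 2014 genes had an unadjusted p below 0.05 where 941 would be expected by chance. The count was 0 without control replicate 1, 2 or 3, it was 4, 1, 2 and 8 without tumour day 10 replicates 1, 2, 4 and 5, and 11 without tumour day 17 replicate 4. It was also 0 in the later run, 0 with the thalamus marker mean as a covariate and 0 without the 4 arrays highest in those markers. In these 2 thalamus fits all 20 genes had the same sign and an unadjusted p below 0.05 (median absolute change 0.76 before, 0.73 and 0.68 in these fits). The genes were selected on arrays that these fits share, so the kept signs and p are no independent support.

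On day 14, the one day with controls of the same day, genes of inflammation, of red cells and of the glucocorticoid response were among those higher. Alas2, which encodes the first enzyme of heme synthesis in red cells, rose by 2.03 ± 0.33 (SE, log2, n = 7 and 4, limma adjusted p = 0.00738), and Slc4a1, the anion exchanger of the red cell membrane, rose by 1.69 ± 0.34. Lcn2 rose by 2.27 ± 0.37, Rsad2 by 1.68 ± 0.31 and Tent5c by 1.61 ± 0.28. Acer2 rose by 1.46 ± 0.20, Vwf by 1.44 ± 0.25, Isg20 by 1.38 ± 0.23 and Ube2l6 by 1.17 ± 0.23. Whether the rises of Rsad2, Tent5c, Isg20 and Ube2l6 came from blood or from tissue was not tested. Of 24 glucocorticoid-responsive genes, 7 rose, or 15 adjusted over the list alone, among them Zbtb16 (1.18 ± 0.19), Map3k6 (0.65 ± 0.10) and Hif3a (0.91 ± 0.16). That list was called higher (camera adjusted p = 1.09e-18), with adjusted p = 0.0421 with an estimated correlation. Of 41 acute-phase and cytokine genes, 36 interferon-stimulated genes and 4 measured red cell markers, 4, 2 and 2 rose, or 8, 14 and 2 adjusted over the list alone. These lists were called higher (camera adjusted p = 7.69e-10, 3.83e-15 and 1.03e-05), with adjusted p = 0.0626, 0.0642 and 0.0626 with an estimated correlation. Circulating leukocyte markers were called higher too (12 of 14 with a higher mean, 0 past the threshold in limma, 0 adjusted over the list alone, camera adjusted p = 0.0238, and adjusted p = 0.306 with an estimated correlation). The mean of that list was 3.50 in controls and 3.59 on day 14, below the background measure of 3.87. Ghsr, the ghrelin receptor gene, rose by 0.48 ± 0.08, and Ghrh, which encodes growth hormone-releasing hormone, rose by 0.69 ± 0.12. The glucose transporter gene Slc2a1 rose by 0.52 ± 0.10 and Ankrd37 by 0.61 ± 0.11, among 17 hypoxia-responsive genes of which 2 rose, or 6 up and 1 down adjusted over the list alone (camera adjusted p = 4.62e-07, and adjusted p = 0.0642 with an estimated correlation). The falls were Nr4a3, an immediate early gene, by 0.73 ± 0.10, the microglial gene Fcrls by 0.43 ± 0.09, Lman2l by 0.37 ± 0.07 and Agpat5 by 0.26 ± 0.05. All 20 cholesterol synthesis genes had a lower mean, 0 of them past the threshold over all genes and 15 adjusted over the list alone, and the list was called lower (camera adjusted p = 9.81e-13, and adjusted p = 0.0414 with an estimated correlation). Among the 24 named genes, which were chosen for passing, all 7 tumour-bearing mice lay beyond every control in 15. In all, limma called 41 genes changed, 37 up and 4 down, and 1970 had an unadjusted p below 0.05. The count was 4, 2 and 2 without control replicates 1, 2 and 3, 109 without control replicate 4 and 25 and 115 without tumour day 14 replicates 5 and 6. It was 0 with only the groups compared in the fit, 0 in the later run, 15 with the thalamus marker mean as a covariate and 0 without the 4 arrays highest in those markers. In these 2 thalamus fits all 41 genes had the same sign and an unadjusted p below 0.05 (median absolute change 0.65 before, 0.66 and 0.56 in these fits). The genes were selected on arrays that these fits share, so the kept signs and p are no independent support.

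**Figure D1:**
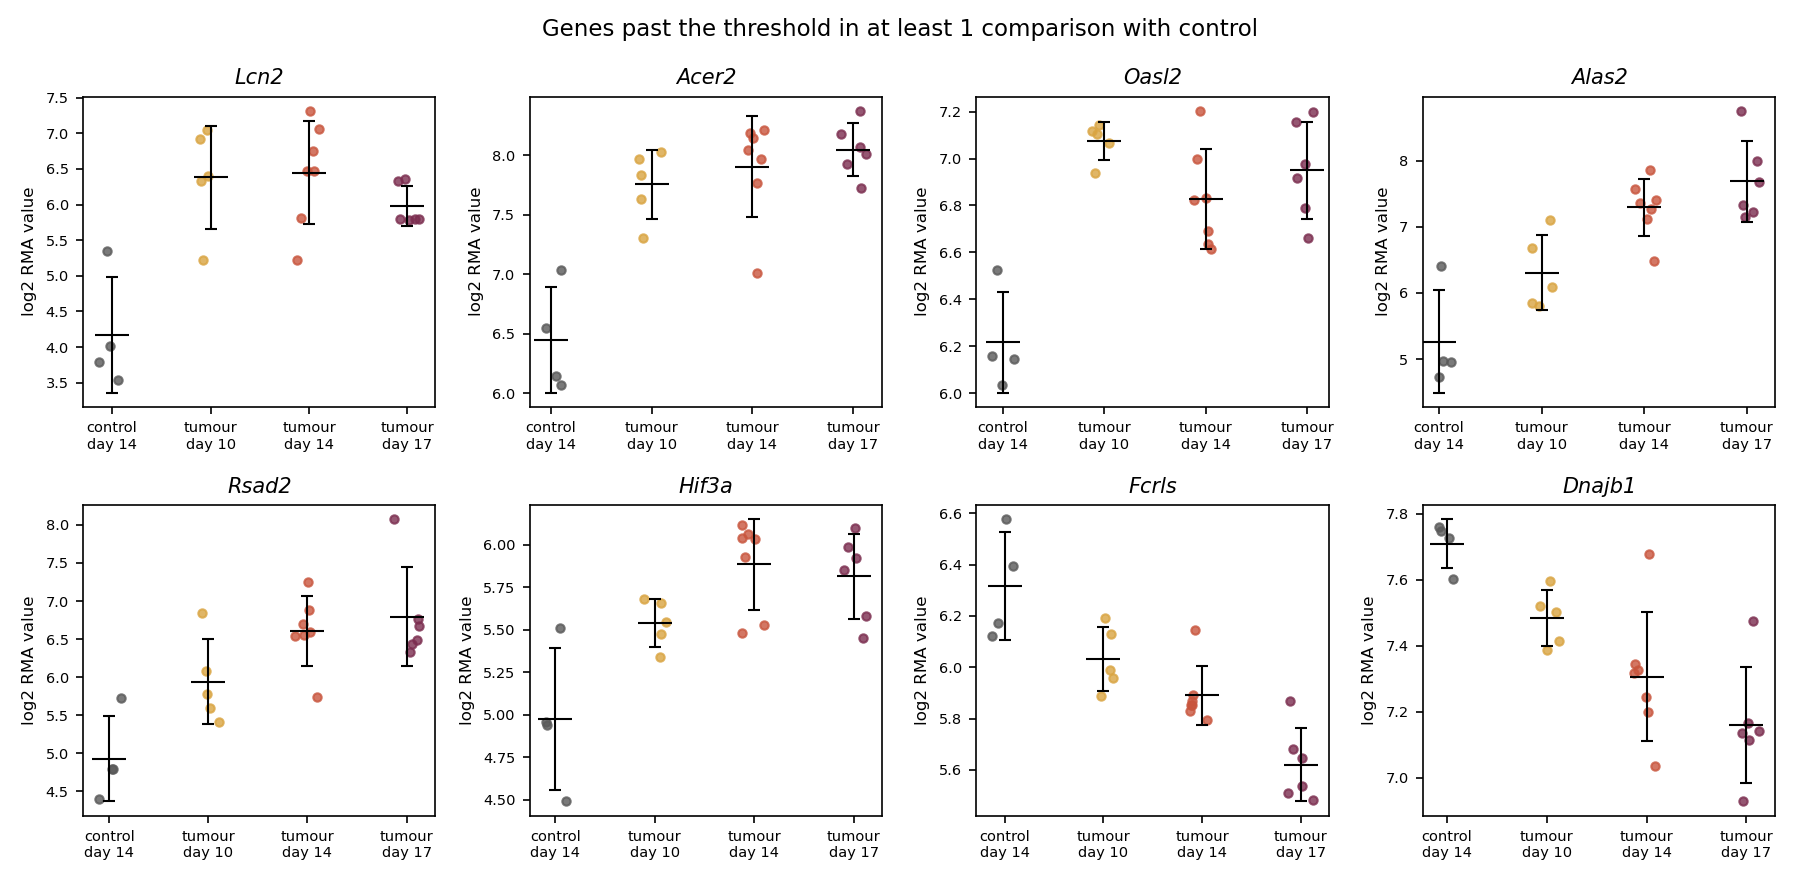
Deposited log2 values of 8 genes (vertical axes) in the 4 groups (horizontal axes), with a point per mouse and bars for the mean ± SD. Alas2 was above every control in each of the 6 mice of tumour day 17, and Fcrls and Dnajb1 were below every control in those 6 mice.

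On day 17, genes of red cells, of inflammation and of the glucocorticoid response were among those higher, and genes of protein folding and sterol synthesis were lower. Alas2 rose by 2.42 ± 0.34 (SE, log2, n = 6 and 4, limma adjusted p = 0.00128), Slc4a1 by 2.10 ± 0.35, Tent5c by 1.96 ± 0.29, Rsad2 by 1.87 ± 0.32, Lcn2 by 1.81 ± 0.38, Isg20 by 1.71 ± 0.23, Acer2 by 1.60 ± 0.21 and Ube2l6 by 1.57 ± 0.23, and Vwf also rose. Npy, which encodes the appetite-stimulating neuropeptide Y, rose by 1.27 ± 0.24, and Ghsr and Ghrh rose by 0.49 ± 0.08 and 0.70 ± 0.12. Ch25h, a cholesterol hydroxylase gene, rose by 1.03 ± 0.18, and the glucocorticoid-induced kinase gene Sgk1 rose by 0.55 ± 0.11. Of 24 glucocorticoid-responsive genes, 41 acute-phase and cytokine genes, 36 interferon-stimulated genes and 4 measured red cell markers, 6, 5, 2 and 2 rose, or 15, 11, 15 and 3 adjusted over the list alone. These lists were called higher (camera adjusted p = 1.65e-13, 6.33e-08, 5.70e-13 and 1.73e-06), with adjusted p = 0.0540, 0.0796, 0.0876 and 0.0540 with an estimated correlation. Among the largest falls were Spink10 by 0.78 ± 0.12, Fabp7, a fatty acid-binding protein of glia, by 0.75 ± 0.13, the neurotensin gene Nts by 0.70 ± 0.13, Fcrls by 0.70 ± 0.09, Kctd21 by 0.62 ± 0.10, Tm6sf2 by 0.55 ± 0.14, Padi2 by 0.53 ± 0.11 and Ncan by 0.53 ± 0.09. The call of Tm6sf2 was lost with a term for the run (limma adjusted p = 0.0533) and in 16 of 22 fits with 1 array left out. Of 14 heat shock protein genes, 6 fell, or 11 adjusted over the list alone, among them Dnajb1 by 0.55 ± 0.10, Hsph1 by 0.54 ± 0.11, Stip1 by 0.36 ± 0.08 and Hspe1 by 0.30 ± 0.06. The list was called lower (camera adjusted p = 1.10e-10), with adjusted p = 0.0540 with an estimated correlation. It was also called lower on days 10 and 14 (camera adjusted p = 0.00889 and 1.18e-08, and adjusted p = 0.478 and 0.0626 with an estimated correlation). Of 20 cholesterol synthesis genes, 3 fell (Cyp51, Sc5d and Dhcr7), or 15 adjusted over the list alone (camera adjusted p = 4.68e-11, and adjusted p = 0.0540 with an estimated correlation), and that list was also called lower on day 10 (camera adjusted p = 5.48e-05, and adjusted p = 0.170 with an estimated correlation). Of 20 genes of the unfolded protein response, 2 fell (Manf and Calr), or 7 adjusted over the list alone (camera adjusted p = 1.14e-05, and adjusted p = 0.0876 with an estimated correlation). Of 71 oxidative phosphorylation genes, 2 fell (Ndufa2 and Ndufs8), or 3 adjusted over the list alone (camera adjusted p = 1.73e-08, and adjusted p = 0.0540 with an estimated correlation). Among the 46 named genes, which were chosen for passing, all 6 tumour-bearing mice lay beyond every control in 43. In all, limma called 211 genes changed, 82 up and 129 down, a split that became 134 up and 55 down with each array centred on its median and 71 up and 77 down after a second quantile normalization. The count was 37, 59 and 56 without control replicates 1, 2 and 3 and 94, 108, 74, 100 and 382 without tumour day 17 replicates 2, 3, 4, 5 and 6. It was 0 in the later run, 88 with the thalamus marker mean as a covariate and 0 without the 4 arrays highest in those markers. In these 2 thalamus fits all 211 genes had the same sign and 211 and 209 an unadjusted p below 0.05 (median absolute change 0.36 before, 0.36 and 0.33 in these fits). The genes were selected on arrays that these fits share, so the kept signs and p are no independent support.

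**Figure D2:**
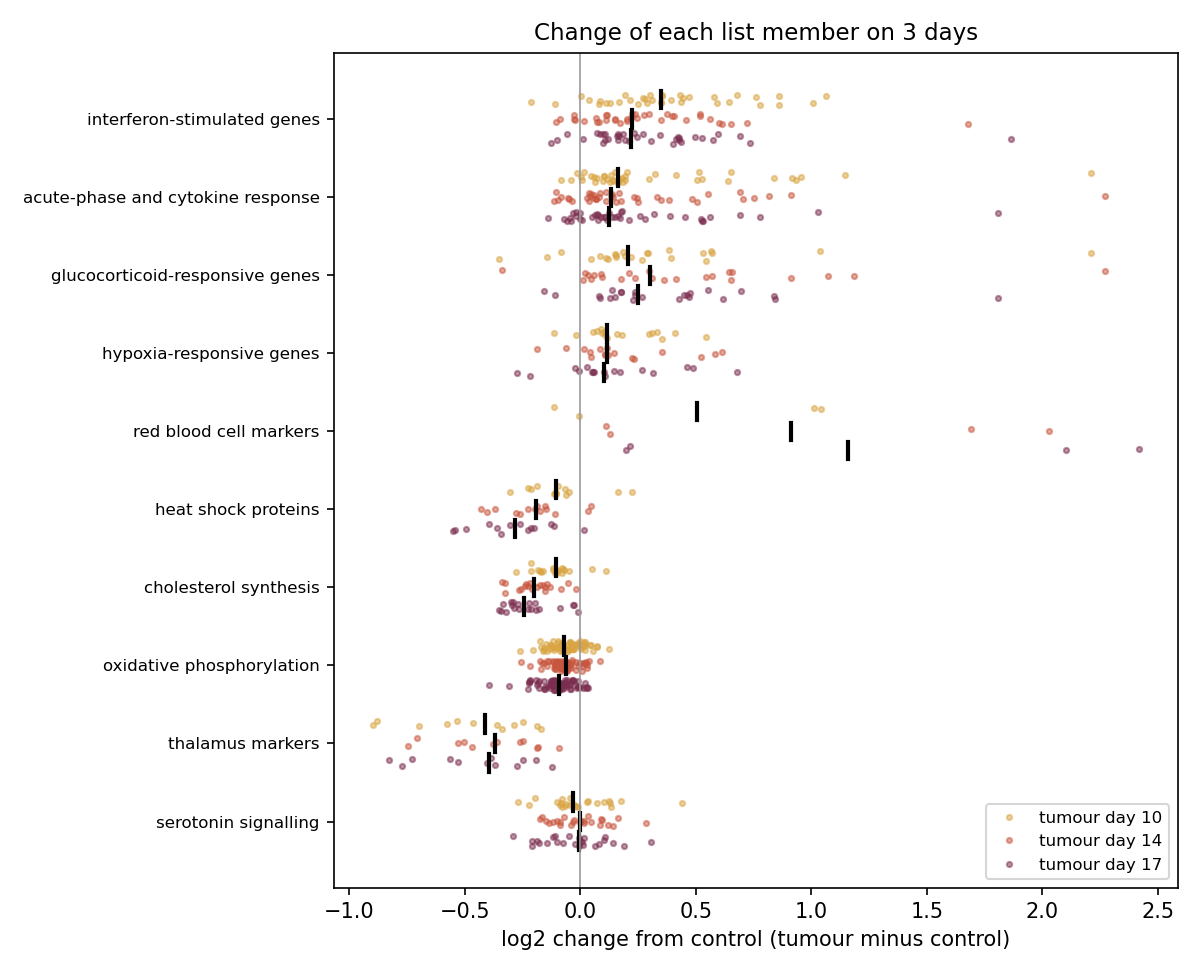
Log2 change from control (horizontal axis) of each measured member of 10 gene lists (vertical axis) on days 10, 14 and 17, with a point per gene and a black bar at the median. All 12 thalamus markers lie below 0 on each day, and the 25 serotonin genes have medians of -0.030, -0.0014 and -0.0067.

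Among tumour-bearing mice, 1 gene was called between days. Nr4a3 was lower on day 14 than on day 10, by 0.67 ± 0.09 (SE, log2, n = 7 and 5, limma adjusted p = 0.00369). With only these groups in the fit, in the later run and in the earlier run limma called 0 genes, and 9 of 100 splits of these arrays, the real one included, gave at least 1. Between days 10 and 17, limma called 0 genes, with 1562 at an unadjusted p below 0.05, and the smallest p belonged to Oacyl (0.53 ± 0.09, adjusted p = 0.0820). Between days 14 and 17, limma called 0 genes, with 785 at an unadjusted p below 0.05. The straight line over days called 0 genes in limma, with 1612 at an unadjusted p below 0.05. As a list, the heat shock protein genes were called lower with day (camera adjusted p = 3.09e-08, and adjusted p = 0.110 with an estimated correlation), with 0 of 14 members past the threshold over all genes and 5 adjusted over the list alone. The appetite-stimulating neuropeptides were called higher with day (camera adjusted p = 0.00337, and adjusted p = 0.110 with an estimated correlation), with 0 of 7 members past the threshold over all genes and 1 adjusted over the list alone. Red cell markers were called higher with day (4 of 4 with a positive slope, 4 adjusted over the list alone). Oligodendrocyte, microglia and meningeal fibroblast markers were called lower (12 of 12, 14 of 15 and 12 of 12 with a negative slope, and 1, 0 and 0 adjusted over the list alone). Over all genes, 0 members of these lists passed. Their camera adjusted p were 4.02e-07, 3.66e-05, 0.000399 and 0.0258, and adjusted p = 0.0921, 0.389, 0.224 and 0.661 with an estimated correlation. The meningeal fibroblast call was lost in 6 of 22 fits with 1 array left out (highest camera adjusted p = 0.461, without tumour day 10 replicate 4). Neuroendocrine, glucocorticoid-responsive, circadian and cytosolic ribosomal protein genes were also called higher with day (camera adjusted p = 0.00444, 0.0183, 0.0486 and 0.000591). With 1 array left out in turn, these calls were lost in 1, 2, 13 and 1 of 22 fits. The neuroendocrine list mean was highest on day 14 (7.21, 7.40 and 7.30 on days 10, 14 and 17). So was the glucocorticoid-responsive mean (7.31, 7.42 and 7.36), and neither rose steadily. Interferon-stimulated, unfolded protein response, cholesterol synthesis, oxidative phosphorylation, astrocyte and ependymal genes were called lower (camera adjusted p = 0.0183, 0.000426, 3.66e-05, 0.0484, 0.0468 and 0.0335). These calls were lost in 4, 0, 0, 9, 6 and 5 of those 22 fits. The interferon-stimulated mean was lowest on day 14 (5.79, 5.69 and 5.71 on days 10, 14 and 17). In all, 16 lists were called with day, and 0 with an estimated correlation. The F test over the 4 groups called 63 genes in limma. That count was 7, 17 and 18 without control replicates 1, 2 and 3, 38, 41 and 96 without tumour day 17 replicates 4, 5 and 6, and 106 without tumour day 14 replicate 6. It was 28 with the thalamus marker mean as a covariate and 0 without the 4 arrays highest in those markers.

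Genes of feeding were examined singly because food intake was the question of the series. Npy differed from control by 0.54 ± 0.25 on day 10 and 0.99 ± 0.24 on day 14 (SE, log2), below the threshold, and the step from day 10 to day 17 was not among the genes called between days. The call on day 17 was lost without control replicate 1, 2 or 3 (highest limma adjusted p = 0.0838). Exact permutation tests of Npy, made in both directions and with smallest possible p of 0.00794, 0.00303 and 0.00476, gave p = 0.167, 0.0121 and 0.00952 on days 10, 14 and 17 (adjusted 0.250, 0.0485 and 0.0485 over 12 tests). Pomc, the precursor of the appetite-reducing melanocortins, differed by -0.65 ± 0.22, -0.33 ± 0.20 and -0.69 ± 0.21 on days 10, 14 and 17, and none of these passed (exact p = 0.0635, 0.236 and 0.0190, adjusted 0.152, 0.315 and 0.0571). Hcrt, the orexin precursor, differed by -0.43 ± 0.22, -0.40 ± 0.21 and -0.33 ± 0.21, and the exact test on day 17 gave p = 0.00952 (adjusted 0.0485), while limma did not call it (adjusted p = 0.456). Cartpt differed by at most 0.07 ± 0.14. Agrp and Pmch were not analysed here.

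**Figure D3:**
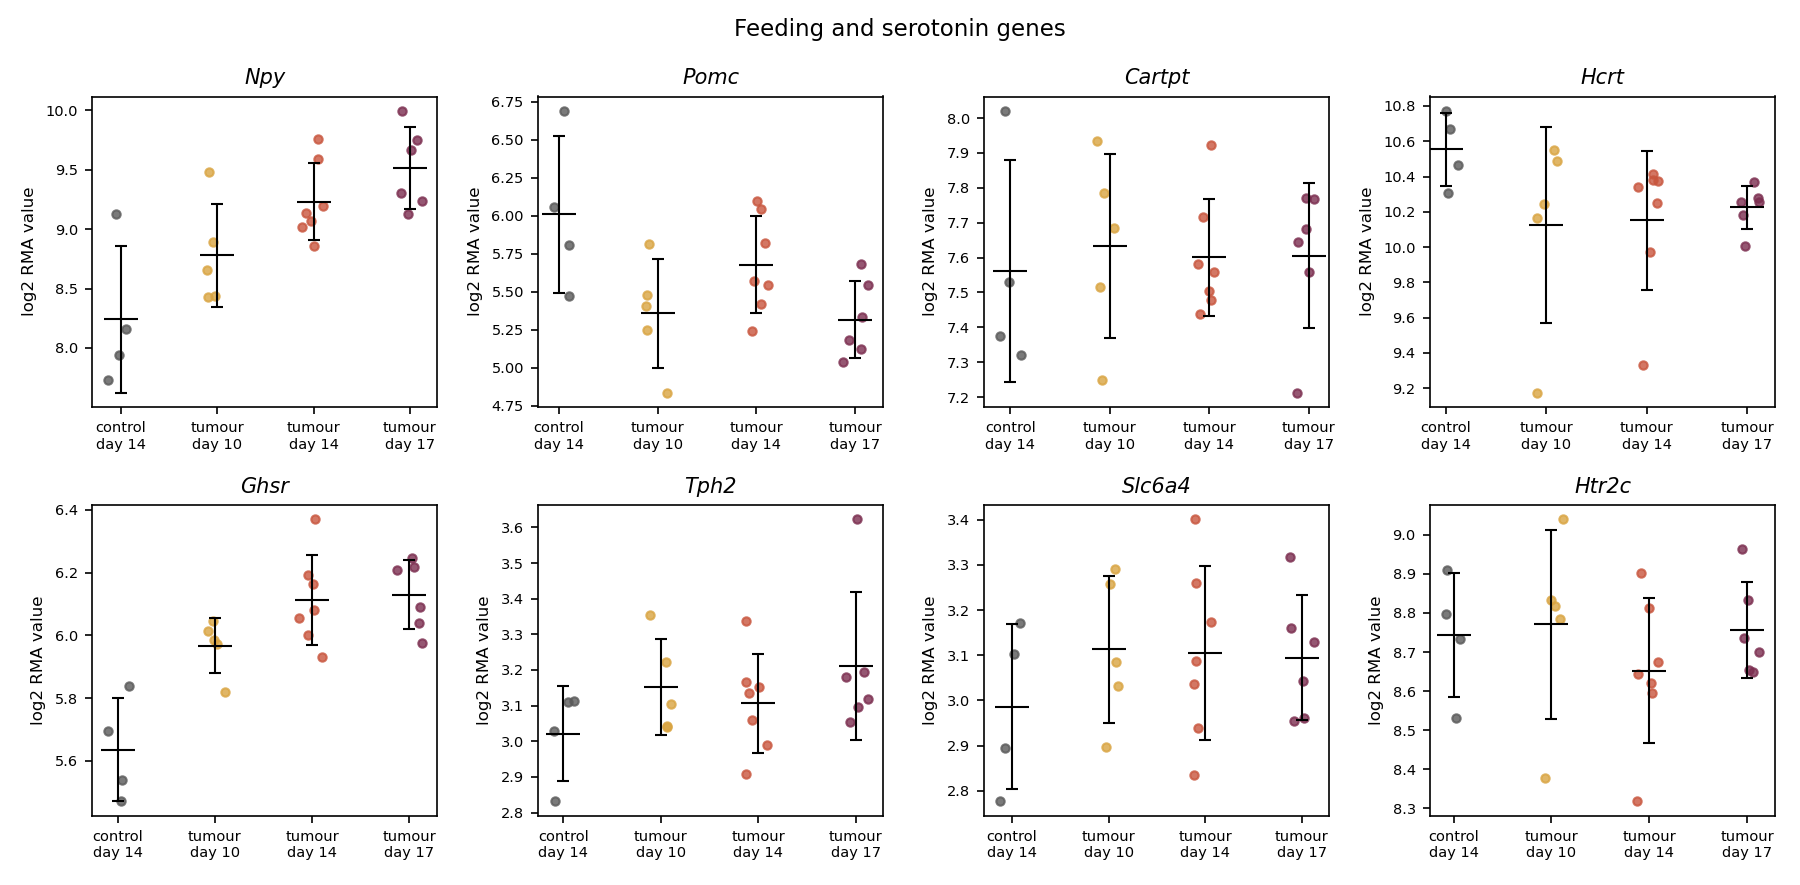
Deposited log2 values of 8 feeding and serotonin genes (vertical axes) in the 4 groups (horizontal axes), with a point per mouse and bars for the mean ± SD. The mean of Npy was 8.24 in controls and 9.51 on tumour day 17.

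Serotonin genes were the subject of the series title. Of 25 measured genes of serotonin synthesis, transport, breakdown and reception, limma called 0 on day 10, 0 on day 14 and 0 on day 17, also 0 adjusted over the list alone and 2, 1 and 3 at an unadjusted p below 0.05, and the list was not called on any of these days (camera adjusted p = 0.557, 0.849 and 0.545). Htr7, a serotonin receptor gene, had the smallest p on day 10, at -0.27 ± 0.09 (SE, log2, limma adjusted p = 0.266). That change was -0.56 in the earlier run, which held 1 control, and -0.15 in the later run. Tph2, the enzyme of serotonin synthesis in neurons, differed by 0.13 ± 0.10, 0.09 ± 0.10 and 0.19 ± 0.10 on days 10, 14 and 17, and the transporter gene Slc6a4 by 0.13 ± 0.11, 0.12 ± 0.10 and 0.11 ± 0.10. Htr2c differed by 0.03 ± 0.11, -0.09 ± 0.11 and 0.01 ± 0.11, and Maoa by -0.03 ± 0.06, -0.03 ± 0.06 and -0.01 ± 0.06. These values do not show that serotonin genes were equal between groups, and Tph2 lay below the background measure of 3.87 on all 22 arrays.

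The 3 comparisons with control shared the same 4 controls. Acer2, Il1r1, Lcn2, Oasl2, Osmr and Zbtb16 passed the threshold on all 3 days. With each of the 22 arrays left out in turn, their calls on day 10 were lost in 6, 12, 7, 3, 12 and 15 fits, with highest adjusted p of 0.118, 0.196, 0.182, 0.0639, 0.182 and 0.196, each without a control. Days 14 and 17 shared 29 rises and 3 falls. With the controls split 2 and 2 between the comparisons, 0 called genes were shared in each of 6 splits, each fit having 2 controls. Leaving out 1 control could already cut the day 14 count to 2, so this 0 decides little. In these splits, 99.5% to 100% of the genes called on day 14 or 17 had the same sign on both days, but they were selected with all 4 controls. Independent lists of the same sizes would share 0.161 and 0.0274, which is no reference for comparisons with common controls. Across genes, which are not independent replicates, the changes of days 14 and 17 correlated at r = 0.839, against a mean of 0.589 and a highest value of 0.828 in 100 simulations of unchanged groups with shared controls. The covariance was 0.0164, against a simulated mean of 0.00623 and a highest of 0.0164. With the controls split 2 and 2, r averaged 0.474 over 6 splits. For days 10 and 14, and days 10 and 17, r was 0.727 and 0.719, against simulated means of 0.602 and 0.550 and highest values of 0.858 and 0.836, and the split controls gave 0.351 and 0.390.

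Markers of neighbouring tissue differed between the arrays. All 12 thalamus markers had a lower mean in each tumour-bearing group than in controls, 0 of them past the threshold in limma and 5, 0 and 4 at an unadjusted p below 0.05 on days 10, 14 and 17, and the list was called lower on days 10, 14 and 17 (camera adjusted p = 1.01e-05, 0.000185 and 0.000429, and adjusted p = 0.310, 0.306 and 0.347 with an estimated correlation). Without control replicate 3, the calls of days 14 and 17 were lost (adjusted p = 0.148 and 0.0948). The marker mean was 6.31 ± 0.57 in controls and 5.84 ± 0.21, 5.92 ± 0.31 and 5.86 ± 0.24 on tumour days 10, 14 and 17 (SD, n = 4, 5, 7 and 6). Control replicates 3 and 1 stood at 7.00 and 6.55, tumour day 14 replicate 2 at 6.61 and tumour day 17 replicate 1 at 6.34. Of 9 ependymal markers, 1 fell on day 17 (Tmem212, by 0.41 ± 0.09), or 4 adjusted over the list alone (camera adjusted p = 0.000665, and adjusted p = 0.190 with an estimated correlation).

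**Figure D4:**
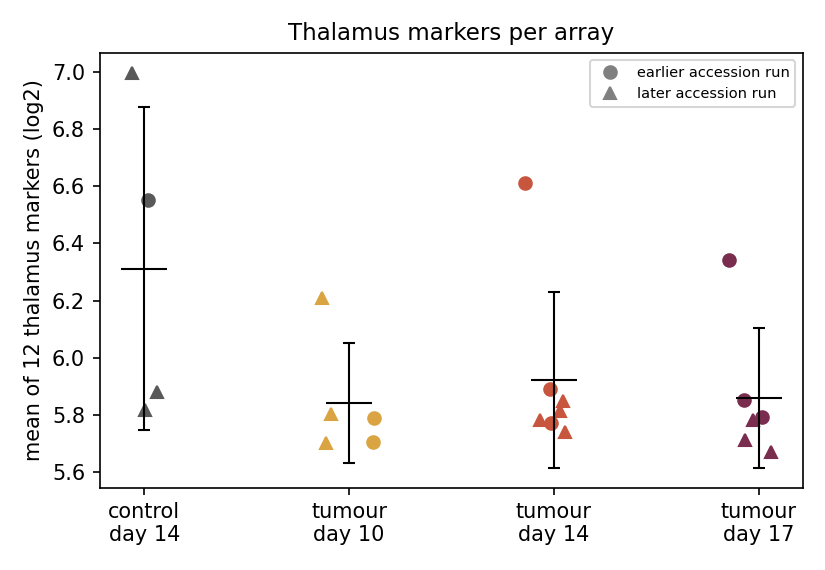
Mean log2 value of 12 thalamus markers (vertical axis) on each of 22 arrays in the 4 groups (horizontal axis), with circles for the earlier and triangles for the later accession run and bars for the mean ± SD. Controls range from 5.82 to 7.00 and tumour day 10 from 5.70 to 6.21.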

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

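Tests chosen only after the results were seen were the term for the run on the genes lower on day 17 and the comparison of the run with random splits; the sizes of the changes with the thalamus covariate were also compared only then, after the count of genes staying past the threshold was known. The 3 patterns were picked from the results, and the criteria of the other tests were set before those tests were run.

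Of 856 sets of a named gene in a group of 4 to 7 arrays, 62 held 1 array far from the rest by Dixon's test. Chance gives about 1 in 20, or 42.8. The sets share 22 arrays and their genes are not independent of each other. The spread of the count around 42.8 is therefore unknown, and 62 against 42.8 is no test. Several flags fall on the same array, such as those of Zbtb16, Ramp3, Tcf7l2, Tbr1, Mag and Tph2 on tumour day 17 replicate 1. Values are log2. In the controls, the single high arrays were those of Ptgs2 at 5.05 (replicate 4), Alas2 at 6.41 (replicate 4), Kctd21 at 6.73 (replicate 1), Dnajc3 at 8.14 (replicate 4), Vim at 9.25 (replicate 4), Lamp5 at 6.91 (replicate 1), Mia at 4.11 (replicate 1) and Cry1 at 6.27 (replicate 1). In the controls, the single low arrays were those of Kcns2 at 5.59 (replicate 2), Bcl3 at 4.08 (replicate 1), Tgm2 at 5.46 (replicate 2), Emcn at 6.56 (replicate 4) and Dio2 at 5.45 (replicate 2). In the tumour day 10 group, the single high arrays were those of Slc4a1 at 6.51 (replicate 4), Nts at 7.20 (replicate 5), Dnajc3 at 8.18 (replicate 1), Egr2 at 4.50 (replicate 1), Ldha at 10.75 (replicate 1), Ctss at 7.62 (replicate 1), Myh11 at 5.79 (replicate 4), Aqp4 at 9.28 (replicate 1) and Clic6 at 6.10 (replicate 3). In the tumour day 10 group, the single low arrays were those of Ifi27l2a at 4.62 (replicate 3), Chac1 at 5.63 (replicate 2), Ankrd37 at 5.83 (replicate 5), Cyp51 at 7.52 (replicate 2), Ugt8a at 8.50 (replicate 3), Flt1 at 7.84 (replicate 3), Insr at 7.86 (replicate 1), Rpl12 at 10.83 (replicate 1) and Hcrt at 9.17 (replicate 3). In the tumour day 14 group, the single high arrays were those of Fcrls at 6.14 (replicate 6), Padi2 at 6.75 (replicate 1), Htr7 at 6.92 (replicate 2), Arc at 5.94 (replicate 2), Ldha at 10.77 (replicate 1), Ramp3 at 6.09 (replicate 2), Tcf7l2 at 8.12 (replicate 2), Htr5b at 4.58 (replicate 1) and Nucb2 at 7.83 (replicate 7). In the tumour day 14 group, the single low arrays were those of Acer2 at 7.01 (replicate 6), Ankrd37 at 5.51 (replicate 6), Slc2a1 at 10.11 (replicate 6) and Hcrt at 9.33 (replicate 3). In the tumour day 17 group, the single high arrays were those of Zbtb16 at 8.48 (replicate 1), Slc4a1 at 7.72 (replicate 3), Rsad2 at 8.07 (replicate 3), Glrp1 at 3.25 (replicate 2), Nr4a1 at 7.40 (replicate 2), Egr2 at 4.72 (replicate 6), Rps3 at 9.55 (replicate 3), Ramp3 at 6.00 (replicate 1), Tcf7l2 at 7.85 (replicate 1), Tbr1 at 4.33 (replicate 1), Dio2 at 6.41 (replicate 5), Chordc1 at 8.48 (replicate 6), Mag at 9.35 (replicate 1) and Tph2 at 3.62 (replicate 1). In the tumour day 17 group, the single low arrays were those of Ptgs2 at 5.18 (replicate 3), Crh at 3.33 (replicate 6), Qrfp at 4.65 (replicate 1) and Kcnj8 at 5.15 (replicate 1).

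Nr4a3 differed between tumour days 14 and 10 by -0.67 in a test of the difference itself. Probe sets outside the gene table also passed the threshold in comparisons with control. Among those paired with several genes, 7 passed on day 10, 5 on day 14 and 13 on day 17. Among those with no gene listed here, 3 passed on day 14 and 6 on day 17.

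Alas2 and Slc4a1 rose on days 14 and 17, the passing genes among 4 measured of 12 listed red cell markers, a list called higher on both days (camera adjusted p = 1.03e-05 and 1.73e-06, and adjusted p = 0.0626 and 0.0540 with an estimated correlation). A term for the run left Alas2 past the threshold on day 17 (limma adjusted p = 0.00162), which argues against the run as the whole cause. A second list of 35 erythroid genes left out genes already seen, among them Alas2, Slc4a1, Isg20, Tent5c, Ube2l6, Rsad2 and Acer2. Its median lay at percentile 98.7 of 10000 matched random lists on day 17. That median was small (0.04, log2), 20 of 35 genes had a higher mean and 2 rose past the threshold. The random lists were matched on mean level and do not carry the correlation between genes. Some members were bright over all arrays (mean of Bnip3l 10.7 and of Prdx2 9.81). Others lay below the background measure of 3.87 (Gata1 at 2.88 and Rhd at 2.93). Such members may show little of a change in blood. The percentile met the criterion set beforehand, but this list is a weak measure. RNA of young red cells in the blood within the tissue may contribute, on weak evidence. More blood of unchanged makeup stays open. The median change of the 8 globin probe sets was 0.93, below 0.5 of the Alas2 change but by less than 2 standard errors. That median mixes 4 bright probe sets, which changed by 1.56 to 1.66, above 0.5 of the Alas2 change, with others near background. In a fit of all probe sets, these 4 bright ones passed the threshold on day 17 (limma adjusted p = 0.00425 to 0.00617). More blood also needs leukocyte markers to be higher. They were called higher on day 17 (camera adjusted p = 0.00925, and adjusted p = 0.237 with an estimated correlation). Their mean of 3.50 in controls and 3.61 on day 17 lay below the background measure of 3.87, so they decide nothing. The explanations cannot be told apart here. Alas2 changed by 1.04, 2.03 and 2.42 on days 10, 14 and 17. Isg20 (0.74, 1.38 and 1.71), Tent5c (0.80, 1.61 and 1.96) and Ube2l6 (0.63, 1.17 and 1.57) also changed more on each later day. So did Rsad2 (1.01, 1.68 and 1.87) and Acer2 (1.31, 1.46 and 1.60). Oasl2 (0.86, 0.61 and 0.73) and Ifitm3 (1.06, 0.72 and 0.69) did not. None of these steps between days was called. Whether these rises came from blood or from tissue was not tested.

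Heat shock genes were lower and Rbm3, a gene induced by cold, was higher in tumour-bearing mice (1.10 ± 0.17 on day 17, limma adjusted p = 0.00226). The heat shock list kept its call on day 17 with a term for the run (camera adjusted p = 5.93e-10) and with the thalamus marker mean as a covariate (1.46e-09), which by this test with the preset correlation argues against both as the whole cause, while the list had adjusted p = 0.0540 with an estimated correlation and neither term. Cirbp, another cold-induced gene, was higher on day 17 by 0.63 ± 0.11 (adjusted p = 0.00832), and within groups Rbm3 and the heat shock mean correlated over 22 arrays (Pearson r = -0.68, permutation p = 0.00461, and Spearman rho = -0.59, p = 0.00547, 1 relation tested). The correlation was -0.57 without the 2 farthest arrays, and -0.76 and -0.86 in the earlier and later runs. Tumour day 14 replicate 6, with the highest heat shock mean of its group (8.83), was also the single low array of Acer2, Ankrd37 and Slc2a1. A correlation within groups would also arise if mice differed in the size of their whole response. The correlation therefore does not single out temperature. A lower body temperature is a candidate explanation, with temperature itself and the time under anaesthesia not analysed here.

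Of the 129 genes lower on day 17, 123 stayed past the threshold with a term for the run, which argues against the run as the whole cause. With the thalamus marker mean as a covariate 39 stayed, fewer than 0.5 of them, the outcome set beforehand as speaking for thalamus tissue in control arrays. The median change was -0.33 with a median SE of 0.07 before the covariate and -0.32 with 0.08 after it, all 129 genes had an unadjusted p below 0.05 with it, and the calls ended through a larger SE and the adjustment over all genes. These sizes argue against thalamus tissue, as far as the 12 markers measure it, as the whole cause of the falls, although they were compared only after the count was known. The 129 genes were also selected on these same arrays, so their unadjusted p is no independent support. A contribution of thalamus tissue to single genes and the difference in day between controls and this group stay open.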

How the results depend on the processing

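Alternatives chosen only after the data were seen were each run alone, the thalamus marker covariate and the fit without the 4 arrays highest in those markers. Counts of changed genes on days 10, 14 and 17 depended on the settings, with main counts of 20, 41 and 211, 1 between days 14 and 10, 0 in the other comparisons of days, 0 in the trend and 63 over any group. A variance trend gave 93 and 323 on days 14 and 17 and 125 over any group. Array weights gave 76, 120 and 457 on the 3 days, 2 between days 17 and 10, 2 in the trend and 140 over any group. A filter at log2(20) gave 68 and 326 on days 14 and 17, 1 between days 17 and 10, 1 in the trend and 10 called lists in the trend in place of 16, and the receptor background filter gave 68 on day 14 and 1 in the trend, with fewer genes tested in both. Every probe set gave 3 and 125 on days 10 and 17 and 39 over any group, with more probe sets tested. Only the groups compared gave 0 on day 14, 81 on day 17 and 0 between days 14 and 10, with fewer samples. The replicate number as a block gave 140 and 616 on days 14 and 17, 19 between days 17 and 10, 22 in the trend and 153 over any group, but the numbers were not taken to pair the mice, since only 15 of 28 same-numbered pairs correlated above 0.1 (range -0.19 to 0.35) and 5 of 22 samples correlated best with their own number. A run term gave 2 in the trend, and 24, 49 and 263 on days 10, 14 and 17, sharing 20, 39 and 196 calls with the fit without it. An adjusted p below 0.01 gave 1, 15 and 35 on the 3 days and 10 over any group. An unadjusted p gave 2014, 1970 and 3131 on the 3 days, 1341, 1562 and 785 between days (14 and 10, 17 and 10, 17 and 14), 1612 in the trend and 2216 over any group. Called lists on days 10, 14, 17 and in the trend, 13, 17, 17 and 16, became 0, 2, 0 and 0 with an estimated correlation (glucocorticoid-responsive genes and cholesterol synthesis on day 14). They became 8, 10, 14 and 6 with fry's directional test and 7, 14, 19 and 6 with its mixed test. The thalamus covariate gave 0, 15 and 88 on the 3 days and 28 over any group. Without the 4 arrays highest in those markers, 0, 0 and 0 genes were called on the 3 days and 0 over any group in limma, with 11 lists on day 14, and all 20, 41 and 211 called genes had the same sign, 20, 41 and 209 of them with an unadjusted p below 0.05. The later run gave 0, 0 and 0 on the 3 days, 0 between days 14 and 10 and 0 over any group in limma, and the earlier run, with 1 control, gave 1, 1 and 1, 0 between days 14 and 10, 1 over any group and 8 lists in the trend. All called genes had the same sign in either run. They were selected on all arrays together, so the signs and p kept in either run or without the 4 arrays are no independent support. Fewer samples and controls enter these fits; beyond that the cause was not tested. Leaving out 1 array gave 0 to 25, 2 to 115 and 37 to 382 on the 3 days, 1 to 1 between days 14 and 10, 0 to 12 between days 17 and 10, 0 to 1 between days 17 and 14, 0 to 8 in the trend and 7 to 106 over any group, and 12 to 18, 14 to 21, 14 to 18 and 12 to 17 called lists on days 10, 14, 17 and in the trend. The lowest counts came without a control: 0, 4 and 37 without control replicate 1, 0, 2 and 59 without replicate 2, and 0, 2 and 56 without replicate 3 on the 3 days, with 7, 17 and 18 over any group. Without control replicate 4 the day 14 count was 109. Without tumour day 10 replicates 1, 2, 4 and 5 the day 10 count was 4, 1, 2 and 8, and without tumour day 17 replicate 4 it was 11. Without tumour day 14 replicates 5 and 6 the day 14 count was 25 and 115, with 106 over any group without replicate 6. Without tumour day 17 replicates 2, 3, 4, 5 and 6 the day 17 count was 94, 108, 74, 100 and 382, with 38, 41 and 96 over any group without replicates 4, 5 and 6. The trend called 1 without tumour day 10 replicate 1, 2 without its replicate 4, and 2 and 8 without tumour day 17 replicates 2 and 6; days 17 and 10 differed in 2 and 12 genes without tumour day 10 replicate 4 and tumour day 17 replicate 6, and days 17 and 14 in 1 gene without tumour day 17 replicate 2 or tumour day 14 replicate 6. Sign changes occurred only among genes that had not passed and in the thalamus list. With array weights, the values became Htr1b 0.035 on day 14. With median centring, the values became Htr1b 0.00829 on day 14 and Maoa 0.026 on day 17. With a second quantile normalization, the values became Htr1b 0.020 on day 14 and Maoa 0.016 on day 17. With the replicate number as a block, the values became Htr1b 0.000383 on day 14 and Maoa 0.00161 on day 17. With a run term, the values became Htr2c -0.00775 on day 17. With the thalamus covariate, the values became Cartpt -0.079 on day 10, -0.086 on day 14 and -0.10 on day 17, Htr1a -0.043 on day 10 and -0.012 on day 17, Htr2a -0.041 on day 10 and -0.035 on day 17, Htr2c 0.016 on day 14 and Maoa 0.00465 on day 17. Without the 4 arrays highest in thalamus markers, the values became Fshb 0.062 on day 14, Ramp3 0.093 on day 14, Cartpt -0.14 on day 10, -0.16 on day 14 and -0.18 on day 17, Htr1a -0.00863 on day 10, Tph2 -0.00125 on day 14, Maoa 0.00771 on day 14 and 0.013 on day 17 and Htr7 0.022 on day 14. In the later run, the values became P2ry12 0.028 on day 17, Neurod2 0.00107 in the trend, Cartpt -0.000836 on day 10, -0.024 on day 14 and -0.11 on day 17, Htr1a -0.00766 on day 10 and -0.057 on day 17, Htr2c -0.011 on day 10, Tph2 -0.057 on day 14 and Htr1b 0.00323 on day 14. In the earlier run, the values became Col1a1 0.19 on day 17, Syn2 0.00388 in the trend, Zic4 0.029 in the trend, Elane 0.00144 in the trend, Slc6a4 -0.11 on day 10 and -0.042 on day 14, Maoa 0.018 on day 10, 0.031 on day 14 and 0.057 on day 17 and Htr2c -0.14 on day 17. Over single arrays left out, the ranges that crossed 0 were Cartpt -0.00742 to 0.23 (day 10), Cartpt -0.041 to 0.19 (day 14), Cartpt -0.036 to 0.20 (day 17), Htr1a -0.020 to 0.060 (day 10), Htr1b -0.13 to 0.00732 (day 10), Htr1b -0.067 to 0.067 (day 14), Htr1b -0.11 to 0.020 (day 17), Htr2c -0.043 to 0.13 (day 10), Htr2c -0.057 to 0.068 (day 17), Maoa -0.077 to 0.00741 (day 10), Maoa -0.078 to 0.00697 (day 14), Maoa -0.053 to 0.031 (day 17) and Zic4 -0.027 to 0.00149 (the trend). The thalamus list, called lower before, had signed adjusted p of 0.59, 0.56 and 0.48 on the 3 days with its own mean as a covariate, which follows from that construction, and 0.96 on day 10 without the 4 arrays. Signal near the receptor background limits Tph2 and other dim genes.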

Other observations

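The test of the run against random splits was chosen after the result was seen. Beyond the groups described so far, 57 of 68 cytosolic ribosomal protein genes had a higher mean on day 14, with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 1.63e-05, and adjusted p = 0.306 with an estimated correlation). On day 17, Rps20 rose by 0.19 ± 0.04 (SE, log2, limma adjusted p = 0.0264), as 1 of those 68 genes. Of 21 immediate early genes, Nr4a3 fell on day 14, or 5 fell adjusted over the list alone (camera adjusted p = 8.10e-06, and adjusted p = 0.0811 with an estimated correlation), and Jun fell by 0.28 ± 0.06 on day 17. Lamp5, a marker of cortical neurons, fell by 0.49 ± 0.08 on day 17, as 1 of 12 cortex and hippocampus markers, a list that was not called (camera adjusted p = 0.173). With the preset correlation, the appetite-reducing neuropeptides were also called lower on day 10 (camera adjusted p = 0.0134, and adjusted p = 0.0823 with an estimated correlation). Oligodendrocyte markers were called lower on days 14 and 17 (camera adjusted p = 0.0147 and 0.0488), and oligodendrocyte precursor markers on day 17 (0.0362). Synaptic genes were called lower on days 10, 14 and 17, and mural cell markers higher on day 14. Tanycyte genes were called higher on days 14 and 17 (camera adjusted p = 0.0195 and 0.0488). With 1 array left out in turn, the oligodendrocyte and tanycyte calls were each lost in 3 of 22 fits on day 14 and 9 on day 17. The precursor call was lost in 3 fits and the mural call in 1. Oxidative phosphorylation genes were also called lower on days 10 and 14 (camera adjusted p = 2.10e-05 and 9.82e-07), and unfolded protein response genes on day 14 (0.00347). Hypoxia-responsive genes were called higher on days 10 and 17 (6.58e-07 and 0.000665), and cytosolic ribosomal protein genes on day 17 (1.89e-05). With an estimated correlation all of these list calls were lost. Among hypoxia-responsive genes past the threshold on day 17, Slc2a1, Ldha and Ankrd37 rose by 0.49, 0.27 and 0.46. Pfkfb3 fell by 0.27 (limma adjusted p = 0.0478). With 1 array left out in turn, the calls of Slc2a1, Ldha, Ankrd37 and Pfkfb3 were lost in 4, 15, 13 and 16 of 22 fits. Lists of appetite-stimulating neuropeptides, feeding receptors, dopamine, neuroendocrine, circadian, astrocyte, endothelial, choroid plexus, pituitary, striatum and hypothalamic transcription factor genes were not called against control on any of these days.

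Other splits of the same arrays were drawn to ask how often chance gives as many calls. For changed genes, 1 of 100 splits, the real one, gave as many on day 10 (20, highest other 3), on day 17 (211, highest other 28) and over any group (63, highest other 2). Chance is unlikely there. For day 14, 2 of 100 splits, the real one included, gave at least the 41 observed, and the other gave 54. Chance is less likely for day 14 but not excluded, and with only the groups compared in the fit limma called 0 genes. For day 14 against day 10, 9 of 100 splits gave at least 1 (highest other 4), so chance cannot be excluded. With 0 genes observed for day 17 against day 10, day 17 against day 14 and the trend, every split gives as many (100 of 100), so the splits decide nothing there, and the highest others were 5, 262 and 27. The split that called 262 genes may point to a structure of the samples, and what its arrays shared was not tested.

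For called gene lists, chance could not be excluded in any comparison with control. As many lists were called in 21 of 100 splits on day 10 (13 observed, highest other 18), 6 of 100 on day 14 (17 observed, highest other 21) and 5 of 100 on day 17 (17 observed, highest other 20). For the trend, 4 of 100 splits, the real one included, gave as many as the 16 observed, with a highest other of 16. Chance is less likely there, but only by a narrow margin and among several such tests. With an estimated correlation, 0 lists were called in the trend. The number of called lists with the preset correlation is therefore weak evidence, whereas the counts of single genes on those days exceeded nearly all splits.

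The arrays differed between the earlier and the later run of accessions. A term for the run called 2272 genes, and 1 of 100 random splits of the same sizes within groups, the real one, gave as many (highest other 216), so a batch of unknown kind may follow the runs. Both runs held all 4 groups, with 1 control in the earlier run and 3 in the later.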
